A study of Homo sapiens with 8 samples.

How the data were processed

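RNA from MCF-7 cells was sequenced in 8 libraries. Per the labels, cells were infected with a lentivirus for wild-type or RNAi-resistant exportin-6 and selected with G418, then infected with an shRNA lentivirus and selected with puromycin, and total RNA was taken with TRIzol and RNeasy. The authors ran bcl2fastq, aligned reads to hg38 with STAR 2.5.1a and counted them per gene with Subread featureCounts 1.4.6-p5. Parameters, annotation release, strand setting and the handling of reads that map to several genes are not stated, so overlapping and antisense genes and close paralogs can share reads. Per the file headers, each library has 1 table with raw counts, CPM and RPKM for 37416 genes. The deposited CPM values equal the counts scaled to the column total, and the deposited RPKM values equal CPM per kilobase of the gene length given; neither was used in a test.

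Libraries held 15409660 to 37651899 counts, and 7 of the 8 held at least 35242715. Gene symbols and biotypes came from GENCODE release 29, which holds 34265 of the gene IDs (31357 at the same start and end); 19479 genes in the files were protein-coding. GC content was taken from the longest transcript of each gene, and 98.0% of tested genes had a value. Samples were grouped by transgene and shRNA as the labels give them. Replicate numbers did not pair the samples: correlations of the deviations of same-numbered libraries lay between -0.0239 and 0.0397.

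Counts were tested with edgeR 4.0.16 (quasi-likelihood, QL, in R 4.3.3) after TMM scaling and filterByExpr with a minimum count of 10, which kept 17542 genes. All 8 libraries entered 1 fit with 4 group means, which left 4 residual degrees of freedom; the prior degrees of freedom were 5.06 and the common biological coefficient of variation was 0.118. The 5 comparisons were knockdown in WT cells, knockdown in RNAi-resistant cells, the difference of these effects (WT minus RNAi-resistant), and RNAi-resistant against WT cells under shXPO6 and under shLUC. P-values were two-sided and adjusted by Benjamini-Hochberg (BH) over all genes tested, and a gene was called at an adjusted p under 0.05. Rose, fell, higher and lower are used of called genes. Log2 fold changes and folds are fitted values, given with SE on the log2 scale, and can differ from the ratio of the levels, which are mean ± SD of CPM after TMM scaling.

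Gene lists were tested in the first 3 comparisons with camera (limma 3.58.1) on log2 CPM with a prior count of 1 and a preset correlation of 0.01, beside camera with an estimated correlation and fry; adjusted p-values were taken over the lists of a comparison, and a list needed at least 5 tested genes. The 26 lists (543 genes, of which 535 matched the files and 495 passed the filter) were: nuclear actin and profilin transport, MRTF-SRF targets, immediate early genes, YAP-TEAD targets, MLL-ENL targets of leukaemia, super elongation complex and MLL subunits, MYC targets in ribosome biogenesis and metabolism, E2F targets in DNA replication, mitosis genes, p53 targets, oestrogen receptor targets, luminal epithelial markers, mesenchymal and basal markers, interferon response genes, ATF4 and unfolded protein response genes, hypoxia and glycolysis genes, cholesterol synthesis genes, NF-kB and inflammatory cytokine genes, apoptosis regulators, cell adhesion and extracellular matrix genes, mitochondrially encoded mRNAs, replication-dependent histone genes, small nuclear and nucleolar host RNAs, fibroblast and stromal markers, blood and endothelial cell markers, HEK293 packaging line markers. The last had too few tested genes, so 25 lists were tested. List members were also called by edgeR with p-values adjusted over all genes and adjusted over the list alone. The lists, comparisons, tests and rule for naming genes were fixed before the data were examined.

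Genes were named by this rule: XPO6, PFN1, PFN2, ACTB, IPO9 and MYC in every comparison; the 10 risen and 10 fallen protein-coding genes with the largest change in each of the first 3 comparisons and 5 each way in the last 2 (called, mean log2 CPM of at least 1, a symbol, replicates of the groups not overlapping); and up to 4 members of each list with the smallest p. Other names carry the words chosen after values were seen.

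Alternatives were the DESeq2 size factors (RLE), library totals alone, no filter on low counts, a CPM of at least 1 in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, fits to the 4 libraries of a comparison, a replicate block, libraries thinned to the smallest, protein-coding genes alone, each library left out in turn, and, added later, offsets for GC content and length. The workflow was tested on simulated data with 2 libraries per group and the dispersions fitted to these data. In 16989 genes the test of knockdown in WT cells recovered 31.3% of 1.5-fold, 86.6% of 2-fold and 98.5% of 4-fold changes. It made 14 false among 158 calls, and the test of the difference recovered 8.96%, 58.2% and 97.0%. Every simulated group had the same spread, and changes were planted in genes with higher counts. In the data the median absolute log2 difference between replicates was 0.31 in WT_shXPO6 and 0.08 to 0.11 in the other groups. The simulated rates therefore do not carry over to comparisons with WT_shXPO6. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.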

Results

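Gene expression was measured by sequencing of total RNA in MCF-7 cells, an established human breast cancer line that carries the oestrogen receptor. The cells had been infected with a lentivirus for exportin-6, either wild-type (WT) or altered to escape the shRNA against XPO6 (RNAi-resistant, shortened to Res in group names). Exportin-6 carries actin bound to profilin out of the nucleus. Each line then received an shRNA against firefly luciferase (shLUC, the control) or against XPO6 (shXPO6). This made 4 groups of 2 libraries: WT_shLUC, WT_shXPO6, Res_shLUC and Res_shXPO6. Total counts were 35242715 and 36443112 in WT_shLUC, 35575056 and 15409660 in WT_shXPO6, 35683669 and 36821164 in Res_shLUC, and 36963274 and 37651899 in Res_shXPO6. Of 37416 genes in each library, 17542 had enough counts to be tested. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples.

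Replicate 2 of WT_shXPO6 differed from its partner. The median absolute log2 difference between the replicates was 0.31 in WT_shXPO6, against 0.08 in WT_shLUC, 0.08 in Res_shLUC and 0.11 in Res_shXPO6. Over 2-fold differences between replicates were seen for 941 of 13662 genes in WT_shXPO6 and for 82, 66 and 116 genes in the other 3 groups. This library lay at -110.8 on the first principal component, which held 40.9% of the variance, and the other 7 lay between -28.4 and 57.6. Its difference from replicate 1 followed GC content across 13537 genes (Spearman -0.54; genes are not independent replicates). The signal recognition particle RNAs RN7SL1, RN7SL2 and RN7SL3 together took 7.40% and 7.03% of counts in WT_shLUC, 5.96% and 3.01% in WT_shXPO6, 5.42% and 5.06% in Res_shLUC, and 3.91% and 3.93% in Res_shXPO6. The 95% Wilson intervals of these shares reached 0.00864 percentage points to either side at most, and they cover counting error only.

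XPO6 RNA fell in WT cells under its shRNA and, less so, in RNAi-resistant cells. The gene (ENSG00000169180, chromosome 16, 28097979 to 28211920, hg38) was counted as a whole, so its count sums the endogenous transcript and the transgene. Its level was 261 and 249 CPM after TMM scaling in WT_shLUC, 107 and 93.7 in WT_shXPO6, 412 and 417 in Res_shLUC, and 297 and 303 in Res_shXPO6. The group means were 255 ± 8.4, 100.5 ± 9.6, 414 ± 3.4 and 299.9 ± 3.8 CPM (SD, n = 2). In WT cells the log2 fold change was -1.34 ± 0.09 (SE; edgeR QL, BH adjusted p = 3.3e-05). In RNAi-resistant cells it was -0.47 ± 0.09 (adjusted p = 0.0069). This call ended without any 1 of that comparison's 4 libraries but held in a fit to those 4. The difference between these effects was -0.88 ± 0.13 (adjusted p = 0.0058), a call that ended without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.083). Under shXPO6, the RNAi-resistant cells held more XPO6 RNA than the WT cells (1.58 ± 0.09, adjusted p = 1.4e-05), and under shLUC they did too (0.70 ± 0.09, adjusted p = 0.00075).

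**Figure D1:**
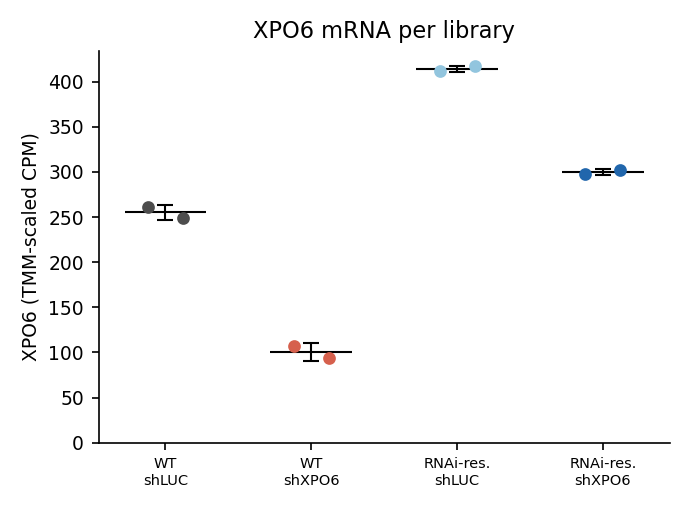
XPO6 RNA in CPM after TMM scaling (linear axis from 0) for the 4 groups: points are the 2 libraries of each group, and bars show the mean ± SD. The RNAi-resistant cells under shXPO6 (297 and 303) sit above the WT cells under shLUC (261 and 249).

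Knockdown in WT cells compares WT_shXPO6 with WT_shLUC. TGM2, the gene of a protein cross-linking enzyme, fell from 42.1 ± 0.16 to 1.06 ± 0.92 CPM (log2 fold change -5.10 ± 0.29, n = 2 per group, edgeR QL, BH adjusted p = 1.5e-05). The oestrogen-induced peptide gene TFF1 fell from 2186 ± 42 to 181 ± 8.1 CPM (-3.59 ± 0.09, adjusted p = 2.6e-07), and the EGFR ligand gene AREG fell 15.6-fold (-3.97 ± 0.13, adjusted p = 1.6e-06). The mucins MUC5AC (-3.98 ± 0.25) and MUC5B (-3.50 ± 0.22), the adhesion proteins CEACAM5 (-4.70 ± 0.20) and CEACAM6 (-3.64 ± 0.27), and KRT81, GCNT1 and AGR2 (-3.52, -3.22 and -2.94) fell with them. These mucins, CEACAMs and keratins have close paralogs, and the handling of reads that map to several genes is not stated. ARHGAP24, a regulator of Rac, rose from 0.430 ± 0.0040 to 11.8 ± 2.5 CPM (4.76 ± 0.27, adjusted p = 1.5e-05). The other large rises were of NPAS3 (log2 fold change 3.39), PCDH19 (3.37), MINAR1 (3.04), TRIB2 (3.01), CDH11 (2.98), FAM171A1 (2.89), CHST1 (2.78), CYP1A1 (2.70) and PLXNA4 (2.69). Without WT_shXPO6 replicate 1, TGM2 stood at -6.71, CEACAM6 at -4.35 and KRT81 at -4.25. CHST1 stood at 2.10 without WT_shLUC replicate 1 and at 4.13 without WT_shLUC replicate 2. CHST1 was not called in a fit to the comparison's own 4 libraries (adjusted p = 0.061).

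Most genes of the actin and MRTF-SRF lists fell. ACTB, the beta-actin gene, fell from 7339 ± 440 to 3341 ± 803 CPM (log2 fold change -1.14 ± 0.15, n = 2 per group, edgeR QL, BH adjusted p = 0.0011). The cofilin gene CFL2 (-1.83 ± 0.15), the actin-binding genes TMSB4X (-0.80 ± 0.08) and CAP1 (-0.71 ± 0.08), and PFN2 (-0.86 ± 0.15, adjusted p = 0.0043) fell. Of 18 genes of nuclear actin and profilin transport, 11 fell, 1 rose and 6 did not pass (adjusted over the list alone, 12 fell and 1 rose), with camera adjusted p = 5.5e-06, and adjusted p = 0.36 with an estimated correlation. XPO6, the target of the shRNA, is a member; without it 10 of 17 fell, with camera adjusted p = 3.4e-05 (0.37 with an estimated correlation). TMSB10 was the member that rose (0.56 ± 0.16; chosen after values were seen). Of 26 targets of MRTF-SRF, which is held back by free actin, 16 fell, 1 rose and 9 did not pass (adjusted over the list alone, 17 fell and 1 rose), with camera adjusted p = 5.6e-09, and adjusted p = 0.19 with an estimated correlation. TPM4 (-1.82 ± 0.08), VCL (-1.24 ± 0.10), TPM1 (-1.02 ± 0.08) and CNN2 (-1.04 ± 0.09) fell, and ACTA2 rose (0.99 ± 0.24; chosen after values were seen). Leaving out 1 library ended calls, with no change of sign: PFN2 without WT_shLUC replicate 2 (adjusted p = 0.056), TMSB10 without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.24) and ACTA2 without either WT_shLUC library, either Res_shXPO6 library or WT_shXPO6 replicate 1 (adjusted p up to 0.16). Without WT_shXPO6 replicate 1, TMSB10 stood at 0.21 and ACTA2 at 0.58. PFN2, TMSB10 and ACTA2 were not called in a fit to the comparison's own 4 libraries (adjusted p up to 0.17).

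PFN1, the profilin gene, did not pass (-0.64 ± 0.26, adjusted p = 0.11 by edgeR QL and BH). Its level was 613 and 568 CPM in WT_shLUC, 509 and 247 in WT_shXPO6, 369 and 385 in Res_shLUC, and 363 and 362 in Res_shXPO6. Its log2 fold change was -0.22 without WT_shXPO6 replicate 2 and -1.29 without replicate 1. MYC did not pass (-0.43 ± 0.15, adjusted p = 0.079). It stood at -0.18 without WT_shXPO6 replicate 2 and at -0.78 without replicate 1. IPO9, the importer of nuclear actin, did not pass (-0.18 ± 0.08, adjusted p = 0.16) and stood at -0.24 without WT_shXPO6 replicate 1. Each of these fits holds 1 WT_shXPO6 library and leaves out the spread of that pair, so their p-values are not given. PFN1 was called with no filter on low counts and with GC content and length offsets (adjusted p up to 0.022). IPO9 was called with GC content and length offsets (adjusted p = 0.016). MYC was called with no filter on low counts, by the DESeq2 Wald test, with a replicate block and with GC content and length offsets (adjusted p up to 0.049).

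Targets of the oestrogen receptor were called as a list. Of 24 oestrogen receptor targets, 12 fell, 2 rose and 10 did not pass (adjusted over the list alone, 17 fell and 2 rose), with camera adjusted p = 3.8e-05, and adjusted p = 0.19 with an estimated correlation. Beside TFF1 (-3.59) and AREG (-3.97), XBP1 (-1.57 ± 0.09) and PDZK1 (-1.65 ± 0.17) fell, and the receptor gene ESR1 fell less (-0.42 ± 0.08, adjusted p = 0.0086 by edgeR QL and BH). CA12 (0.66 ± 0.07) and ELOVL2 (0.65 ± 0.11), chosen after values were seen, were the targets that rose. Of 24 targets of p53, 9 rose, 1 fell and 14 did not pass (adjusted over the list alone, 11 rose and 1 fell), with camera adjusted p = 0.0046, and adjusted p = 0.19 with an estimated correlation. CCNG1 (1.32 ± 0.13), PPM1D (0.51 ± 0.08) and BBC3 (0.96 ± 0.17) rose, and ZMAT3 fell (-0.69 ± 0.12). Calls that ended, at the same sign, when 1 library was left out were ESR1, PPM1D and BBC3 without either WT_shLUC library (adjusted p up to 0.093) and ZMAT3 and ELOVL2 without WT_shLUC replicate 2 (adjusted p up to 0.059). BBC3 stood at 0.58 without WT_shXPO6 replicate 1. ESR1, PPM1D, ZMAT3, BBC3 and ELOVL2 were not called in a fit to the comparison's own 4 libraries (adjusted p up to 0.12).

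The lists of MYC, E2F, cholesterol, hypoxia and mitochondrial genes were called too, with changes in part of their members. Of 24 MYC targets in ribosome biogenesis and metabolism, 13 fell, 1 rose and 10 did not pass (adjusted over the list alone, 15 fell and 2 rose), with camera adjusted p = 0.00021, and adjusted p = 0.19 with an estimated correlation. WDR43 (-0.55 ± 0.08), DKC1 (-0.50 ± 0.08) and NOP56 (-0.45 ± 0.08) fell, and the risen member was ODC1 (0.61 ± 0.08). Of 24 E2F targets in DNA replication, 6 fell, 2 rose and 16 did not pass (adjusted over the list alone, 9 fell and 2 rose), with camera adjusted p = 0.018, and adjusted p = 0.19 with an estimated correlation. MCM10 fell (-0.57 ± 0.09); E2F1 (0.45 ± 0.11) and GINS2 (0.30 ± 0.09), chosen after values were seen, rose. Of 23 cholesterol synthesis genes, 6 fell and 17 did not pass (adjusted over the list alone, 7 fell), with camera adjusted p = 0.0057, and adjusted p = 0.19 with an estimated correlation. INSIG1 fell (-0.70 ± 0.08). Of 23 hypoxia and glycolysis genes, 5 fell and 18 did not pass (adjusted over the list alone, 6 fell), with camera adjusted p = 0.019, and adjusted p = 0.19 with an estimated correlation. HK2 fell (-1.12 ± 0.10). The hypoxia test was not called without WT_shXPO6 replicate 2 (adjusted p = 0.062). Of 13 mitochondrially encoded mRNAs, 3 fell and 10 did not pass (adjusted over the list alone, 3 fell), with camera adjusted p = 0.018, and adjusted p = 0.59 with an estimated correlation. The mitochondrial test was not called without WT_shXPO6 replicate 2 (adjusted p = 0.41), without WT_shLUC replicate 1 (0.059), or by fry (0.16). No longer called with 1 library left out, at the same sign, were NOP56 without either WT_shLUC library (adjusted p up to 0.059), E2F1 without either WT_shLUC library or either Res_shLUC library (adjusted p up to 0.16) and GINS2 without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.30). WDR43, DKC1 and MCM10 were not called in a fit to the comparison's own 4 libraries (adjusted p up to 0.067). NOP56 was not called in a fit to the comparison's own 4 libraries or with library totals alone (adjusted p up to 0.080). E2F1 was not called in a fit to the comparison's own 4 libraries or with GC content and length offsets (adjusted p up to 0.12). GINS2 was not called in a fit to the comparison's own 4 libraries, with no filter on low counts, with a replicate block or with libraries thinned to the smallest (adjusted p up to 0.19).

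The interferon, basal, YAP-TEAD and NF-kB lists were called with members that did not pass in each. Of 24 interferon response genes, 10 fell and 14 did not pass (adjusted over the list alone, 10 fell), with camera adjusted p = 0.0030, and adjusted p = 0.19 with an estimated correlation. OAS2 (-1.04 ± 0.11), IFIT1 (-0.93 ± 0.13), MX1 (-1.003 ± 0.15) and STAT1 (-0.48 ± 0.08) fell. Of 17 mesenchymal and basal markers, 7 fell, 2 rose and 8 did not pass (adjusted over the list alone, 7 fell and 3 rose), with camera adjusted p = 0.018, and adjusted p = 0.19 with an estimated correlation. LAMB3 (-1.75 ± 0.11), LAMC2 (-1.54 ± 0.13) and KRT17 (-1.45 ± 0.11) fell, and EGFR (1.66 ± 0.12) and SNAI1 (1.38 ± 0.29; chosen after values were seen) rose. Of 19 YAP-TEAD targets, 6 rose, 3 fell and 10 did not pass (adjusted over the list alone, 9 rose and 4 fell), with camera adjusted p = 0.027, and adjusted p = 0.39 with an estimated correlation. NT5E rose (1.93 ± 0.08), and so did CRIM1 (1.62 ± 0.09). Of 21 NF-kB and inflammatory cytokine genes, 2 rose and 19 did not pass (adjusted over the list alone, 2 rose), with camera adjusted p = 0.022, and adjusted p = 0.19 with an estimated correlation. TNFAIP3 (0.60 ± 0.12) and TNF (2.29 ± 0.49) were the risen members. The YAP-TEAD and mesenchymal tests were not called without WT_shLUC replicate 1 (adjusted p = 0.059 and 0.064) or without WT_shXPO6 replicate 1 (0.14 and 0.19), and the NF-kB test was not called without the latter (0.14). Some calls ended at an unchanged sign with 1 library fewer: STAT1 without WT_shLUC replicate 1 (adjusted p = 0.059), TNFAIP3 without either WT_shLUC library (adjusted p up to 0.12) and TNF and SNAI1 without WT_shLUC replicate 2 (adjusted p up to 0.12). SNAI1 stood at 0.82 without WT_shXPO6 replicate 1, and TNF at 3.61 and 1.57 without WT_shLUC replicates 1 and 2. IFIT1, MX1, STAT1, TNFAIP3, TNF and SNAI1 were not called in a fit to the comparison's own 4 libraries (adjusted p up to 0.15).

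Several lists with members moving both ways did not pass in WT cells. Of 22 immediate early genes, 4 rose and 5 fell (7 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.57); of 18 MLL-ENL targets, 3 rose and 2 fell (3 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.80). Of 22 luminal epithelial markers, 4 rose and 6 fell (6 fell and 5 rose adjusted over the list alone, camera adjusted p = 0.65); and of 23 ATF4 and unfolded protein genes, 5 rose and 8 fell (12 fell and 6 rose adjusted over the list alone, camera adjusted p = 0.27). For the MLL-ENL list the median was -0.03 and the mean 0.17, and for the luminal list they were 0.07 and -0.16, so median and mean differed in sign; the tests pointed up for the former and down for the latter, like the means. The MLL-ENL median ran from -0.20 to 0.08 with 1 library left out, and the luminal median was -0.08 without WT_shXPO6 replicate 1. The luminal and ATF4 lists were called by fry (adjusted p = 0.0065 and 0.021). Mitosis genes were called without WT_shXPO6 replicate 2 (adjusted p = 0.0029), with 4 of 24 fallen (4 adjusted over the list alone, camera adjusted p = 0.10) when all libraries were used.

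In all, 1614 genes rose and 1813 fell in WT cells (edgeR QL, BH), 524 and 390 of them by more than 2-fold. With library totals in place of TMM, 2292 rose and 1113 fell, or 67.3% risen against 47.1%, and the median log2 change of all genes was 0.14 against 0.0097. The fallen members were then 8 for MYC targets and 2 for E2F targets, and the hypoxia median was 0.01 against -0.13. That median was -0.22 without WT_shLUC replicate 2 and -0.36 without WT_shXPO6 replicate 1. Counts were larger without either WT_shXPO6 library and smaller without any other. In a fit to the 4 libraries of this comparison they were 344 and 352. There, 25 of the 76 named genes called in WT cells were not called. All groups share 1 spread, although the WT_shXPO6 pair differed far more than the others. Counts of calls, and overlaps drawn from them, therefore do not show which line responded more. A fit without either WT_shXPO6 library leaves 1 there and takes that pair out of the spread. Its larger counts therefore do not test stability. With an estimated correlation, which rests on 4 residual degrees of freedom, the calls that held were those of the interferon list in RNAi-resistant cells and in the difference between lines.

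Knockdown in RNAi-resistant cells compares Res_shXPO6 with Res_shLUC. Interferon response genes fell. IFI44L fell from 177 ± 3.0 to 7.08 ± 0.86 CPM (log2 fold change -4.64 ± 0.15, n = 2 per group, edgeR QL, BH adjusted p = 5.1e-07). MX2, an antiviral GTPase gene, fell from 225 ± 17 to 9.42 ± 0.20 CPM (-4.58 ± 0.10, adjusted p = 9.4e-08). The other large falls were of RSAD2 (log2 fold change -4.49), IFI44 (-4.36), IFIT3 (-4.22), OAS2 (-3.98), CCL5 (-3.89), CMPK2 (-3.88), APOL1 (-3.68) and CD74 (-3.67). The OAS and IFIT genes have close paralogs, and the handling of shared reads is not stated. Of 24 interferon response genes, 24 fell (24 adjusted over the list alone), IFIT2 among them (-3.60 ± 0.11). The list was called (camera adjusted p = 7.2e-28, and adjusted p = 0.023 with an estimated correlation). FOXI1, a transcription factor gene, rose 11.5-fold (3.52 ± 0.18, adjusted p = 4.1e-06), and the receptor gene GABBR2 rose 10.1-fold (3.34 ± 0.15, adjusted p = 2.4e-06). NPAS3, TRIB2, FAM171A1 and ARHGAP24 rose here as in WT cells (3.02, 2.67, 2.66 and 2.52). The remaining large rises were of GPRC5B (log2 fold change 2.69), HCN4 (2.69), UBE2QL1 (2.64) and MFAP2 (2.55).

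The list of oestrogen receptor targets was called in these cells too. Of 24 oestrogen receptor targets, 15 fell, 2 rose and 7 did not pass (adjusted over the list alone, 18 fell and 2 rose), with camera adjusted p = 1.5e-08, and adjusted p = 0.19 with an estimated correlation. TFF1 (-2.40 ± 0.08), AREG (-3.13 ± 0.12), PGR (-2.18 ± 0.11) and XBP1 (-1.41 ± 0.09) fell. ELOVL2 (1.003 ± 0.11) and CCND1 (0.29 ± 0.08), chosen after values were seen, rose. ESR1 fell (-1.09 ± 0.08), and so did SPDEF (-2.51 ± 0.11). Of 24 p53 targets, 12 rose and 12 did not pass (adjusted over the list alone, 16 rose), with camera adjusted p = 1.4e-07, and adjusted p = 0.11 with an estimated correlation. PPM1D (0.66 ± 0.08), CCNG1 (0.96 ± 0.13) and TP53INP1 (0.61 ± 0.09) rose. Of 24 mitosis genes, 6 fell and 18 did not pass (adjusted over the list alone, 9 fell), with camera adjusted p = 0.0036, and adjusted p = 0.37 with an estimated correlation. CCNA2 fell (-0.49 ± 0.08). Of 23 cholesterol synthesis genes, 4 fell and 19 did not pass (adjusted over the list alone, 5 fell), with camera adjusted p = 0.0022, and adjusted p = 0.28 with an estimated correlation. INSIG1 fell (-0.67 ± 0.08). The following were not called in fits with 1 library fewer, with signs kept: CCNA2 without Res_shLUC replicate 2 or Res_shXPO6 replicate 1 (adjusted p up to 0.070) and CCND1 without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.31).

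**Figure D2:**
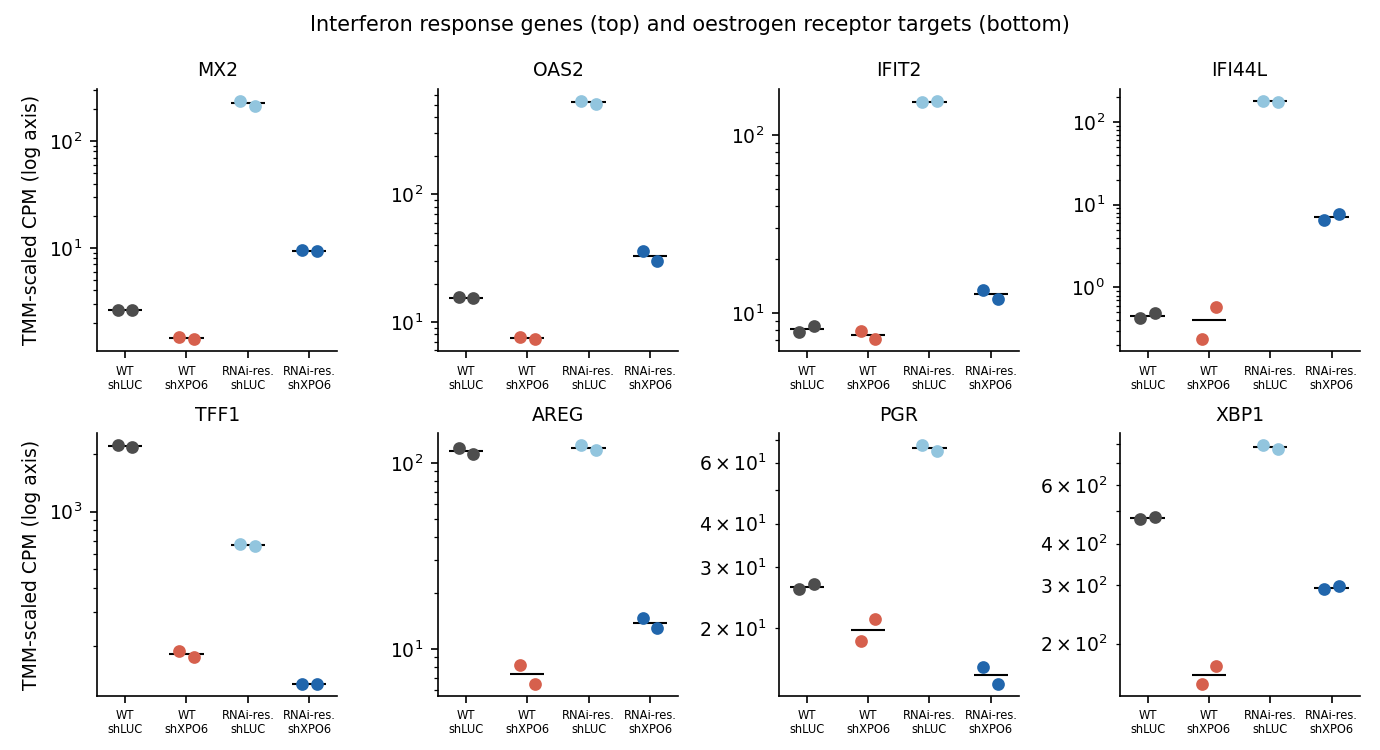
CPM after TMM scaling (log axis) of interferon response genes (MX2, OAS2, IFIT2, IFI44L) and oestrogen receptor targets (TFF1, AREG, PGR, XBP1) in the 4 groups, each point 1 library. The interferon genes stand highest in Res_shLUC, while TFF1, AREG and XBP1 are lower under shXPO6 in both lines.

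In RNAi-resistant cells the actin list was not called, and the MRTF-SRF list was. ACTB (-0.60 ± 0.15, adjusted p = 0.022 by edgeR QL and BH), PFN2 (-0.58 ± 0.14, adjusted p = 0.023) and CFL2 (-0.72 ± 0.14) fell, and PFN1 (-0.05 ± 0.26, adjusted p = 0.92), IPO9 (-0.02 ± 0.08, adjusted p = 0.90) and MYC (-0.28 ± 0.15, adjusted p = 0.27) did not pass. Of 18 genes of nuclear actin and profilin transport, 1 rose and 6 fell (6 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.12), and the list median of -0.07 became 0.01 with library totals alone and -0.12 without Res_shLUC replicate 2. Without XPO6, 5 of 17 fell (camera adjusted p = 0.19). TMSB10 (0.65 ± 0.16; chosen after values were seen) was the risen member. Of 26 MRTF-SRF targets, 11 fell, 1 rose and 14 did not pass (adjusted over the list alone, 13 fell and 2 rose), with camera adjusted p = 0.0038, and adjusted p = 0.37 with an estimated correlation. TPM1 (-1.04 ± 0.08), ACTG2 (-4.07 ± 0.34), TPM4 (-0.91 ± 0.08) and VCL (-0.78 ± 0.10) fell, and ACTA2 rose (0.87 ± 0.24; chosen after values were seen). Leaving out 1 library ended calls, with no change of sign: PFN2, ACTB, TMSB10 and ACTA2 without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.27) and CFL2 without either Res_shLUC library or Res_shXPO6 replicate 2 (adjusted p up to 0.085). MYC was called without either WT_shXPO6 library (-0.28, adjusted p up to 1.6e-06). ACTA2 was not called with libraries thinned to the smallest (adjusted p = 0.059). MYC was called in a fit to the comparison's own 4 libraries (adjusted p = 1.7e-06).

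The immediate early and YAP-TEAD lists were called in RNAi-resistant cells. Of 22 immediate early genes, 8 rose, 1 fell and 13 did not pass (adjusted over the list alone, 11 rose and 1 fell), with camera adjusted p = 0.0036, and adjusted p = 0.37 with an estimated correlation. IER3 (0.96 ± 0.09), FOSL1 (1.07 ± 0.11) and FOSB (1.246 ± 0.21) rose, and KLF4 fell (-0.65 ± 0.12). Of 19 YAP-TEAD targets, 9 rose, 1 fell and 9 did not pass (adjusted over the list alone, 12 rose and 2 fell), with camera adjusted p = 0.0023, and adjusted p = 0.37 with an estimated correlation. NT5E (2.28 ± 0.09), AMOTL1 (1.36 ± 0.09) and CRIM1 (1.04 ± 0.09) rose, and DOCK5 fell (-0.49 ± 0.08; chosen after values were seen). Calls that ended, at the same sign, when 1 library was left out were FOSB without Res_shLUC replicate 1 or Res_shXPO6 replicate 1 (adjusted p up to 0.059), KLF4 without either Res_shLUC library or either Res_shXPO6 library (adjusted p up to 0.097) and DOCK5 without Res_shLUC replicate 2 or Res_shXPO6 replicate 1 (adjusted p up to 0.056). In all, 1456 genes rose and 1487 fell in these cells (edgeR QL, BH), 374 and 496 by more than 2-fold. With library totals alone 1811 rose and 1070 fell, or 62.9% risen against 49.5%. Counts were larger without either WT_shXPO6 library and smaller without any other. In a fit to the 4 libraries of this comparison they were 3744 and 3650. There, 0 of the 61 named genes called in these cells lost their call. With GC content and length offsets 2355 rose.

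The difference of the knockdown effects, WT minus RNAi-resistant, tests whether the response differed between the lines. Most genes called in WT cells moved the same way in RNAi-resistant cells. Of the 3427 genes called in WT cells, 3021 (88.2%) had the same sign there, against 67.3% of all 17542 tested genes. Both comparisons called 758 as risen and 770 as fallen, where lists drawn independently would share 134 and 154. They called 52 as risen in WT and fallen in RNAi-resistant cells, and 26 the other way. The median effect ratio, RNAi-resistant over WT, was 0.596 for the 3427 genes (Spearman 0.76, genes not independent replicates). It was 1.17 for genes called in RNAi-resistant cells. NPAS3 rose by a similar amount in WT (3.39 ± 0.24) and RNAi-resistant cells (3.02 ± 0.25), and its difference did not pass (adjusted p = 0.67 by edgeR QL and BH). TFF1 fell in either line and more so in WT cells (-1.20 ± 0.11, adjusted p = 0.00063 for the difference). Of 336 genes called in WT cells and in the difference, 104 had a smaller effect of the same sign in RNAi-resistant cells, 178 had the opposite sign and 54 a larger effect. The 336 became 659 with no filter on low counts, 554 by the DESeq2 Wald test and 988 with GC content and length offsets, and 69 to 4687 with 1 library left out. Genes called in both knockdowns in the same direction, 1528, became 608 in the fits to 4 libraries, 2418 with the offsets, and 588 to 3948 with 1 library left out.

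**Figure D3:**
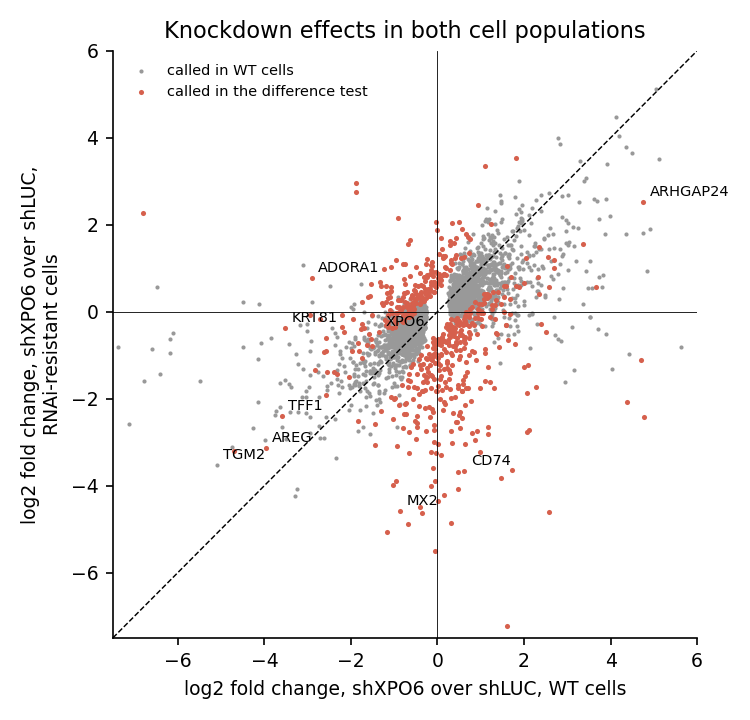
Log2 fold change (shXPO6 over shLUC) in WT cells (x axis) against RNAi-resistant cells (y axis) for 3658 genes, each point 1 gene: grey points were called in WT cells and red points in the test of the difference, and 10 genes lie outside the axes. Most grey points, TGM2 among the labelled genes, lie in the quadrants where both effects have the same sign. MX2 and CD74 lie far below the diagonal.

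Interferon response genes had positive differences. CD74, APOL1, RSAD2 and MX2 fell in RNAi-resistant cells (-3.67, -3.68, -4.49 and -4.58) and stood at 0.62, 0.46, -0.39 and -0.86 in WT cells. Their differences were CD74 (4.29 ± 0.26), APOL1 (4.15 ± 0.23), RSAD2 (4.09 ± 0.30) and MX2 (3.72 ± 0.19) (adjusted p by edgeR QL and BH = 6.9e-05, 5.0e-05, 0.00016 and 3.9e-05). The differences of SECTM1, UBA7, HERC5, TNFSF10, TRANK1 and NLRC5 were 4.01, 3.97, 3.82, 3.59, 3.35 and 3.21. Of 24 interferon response genes, 23 had a higher effect in WT cells and 1 did not pass (adjusted over the list alone, 24 higher), with camera adjusted p = 4.9e-32, and adjusted p = 0.017 with an estimated correlation. IFIT3 (4.37 ± 0.27), IFIT2 (3.50 ± 0.15) and OAS2 (2.95 ± 0.15) had positive differences. In the other direction, ADORA1, an adenosine receptor gene, had the largest difference (-3.67 ± 0.27, adjusted p = 0.00016); KRT81 followed (-3.15 ± 0.31, adjusted p = 0.00073). SPOCK1, PADI3, GABBR2, LOXL2, MMD, S100A16, NAV2 and TNIK lay between -2.55 and -2.10. Without WT_shXPO6 replicate 1, KRT81 stood at -3.88 and SPOCK1 at -3.19. No longer called with 1 library left out, at the same sign, were SPOCK1 without Res_shLUC replicate 1, Res_shXPO6 replicate 1 or WT_shLUC replicate 2 (adjusted p up to 0.062), PADI3 without Res_shLUC replicate 1, Res_shXPO6 replicate 1 or WT_shLUC replicate 1 (adjusted p up to 0.065), MMD without Res_shLUC replicate 1 (adjusted p = 0.0502) and TNIK without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.15). TNIK was not called with libraries thinned to the smallest (adjusted p = 0.095).

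The actin and MRTF-SRF lists were called in the difference, with most members not passing. Of 18 genes of nuclear actin and profilin transport, 3 were lower and 15 did not pass (adjusted over the list alone, 6 were lower), with camera adjusted p = 1.4e-06, and adjusted p = 0.45 with an estimated correlation. Without XPO6, 2 of 17 were lower (camera adjusted p = 9.2e-06, and 0.45 with an estimated correlation). XPO6 (-0.88), TMSB4X (-0.73 ± 0.12) and CFL2 (-1.11 ± 0.20) were the members called, and ACTB (-0.54 ± 0.21, adjusted p = 0.25), PFN1 (-0.59 ± 0.36, adjusted p = 0.48), PFN2 (-0.27 ± 0.20, adjusted p = 0.58), IPO9 (-0.16 ± 0.12, adjusted p = 0.57) and MYC (-0.15 ± 0.22, adjusted p = 0.79) did not pass by edgeR QL and BH. Without WT_shXPO6 replicate 1, ACTB stood at -0.83, PFN1 at -1.24, PFN2 at -0.59 and MYC at -0.50. Without WT_shXPO6 replicate 2 they stood at -0.31, -0.16, -0.04 and 0.10. Either fit holds 1 WT_shXPO6 library, so p-values are not given. Of 26 MRTF-SRF targets, 4 were lower and 22 did not pass (adjusted over the list alone, 11 were lower), with camera adjusted p = 1.4e-06, and adjusted p = 0.41 with an estimated correlation. TPM4 (-0.91 ± 0.11), FHL2 (-1.37 ± 0.27), CCN1 (-0.89 ± 0.19) and CCN2 (-0.998 ± 0.22) were lower. Of 22 immediate early genes, 4 were lower, 2 were higher in WT cells and 16 did not pass (adjusted over the list alone, 10 were lower and 3 were higher in WT cells), with camera adjusted p = 0.0018, and adjusted p = 0.45 with an estimated correlation. IER3 (-1.11 ± 0.12), EGR3 (-1.14 ± 0.15), FOSL1 (-1.21 ± 0.16) and KLF6 (-0.78 ± 0.15) were lower, and BTG2 (0.60 ± 0.12) and KLF4 (0.78 ± 0.17; chosen after values were seen) were higher. The immediate early test was not called by fry (adjusted p = 0.054). Some calls ended at an unchanged sign with 1 library fewer: XPO6, TMSB4X, CFL2, FHL2, CCN1, CCN2, KLF6, BTG2 and KLF4 without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.31). CFL2 and KLF6 were not called with library totals alone (adjusted p up to 0.11). CCN2 was not called with a replicate block (adjusted p = 0.058). BTG2 was not called with library totals alone or with libraries thinned to the smallest (adjusted p up to 0.070). PFN1 was called with no filter on low counts (adjusted p = 0.039). ACTB was called with no filter on low counts and with GC content and length offsets (adjusted p up to 0.024).

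Other lists were called in the difference as well. Of 24 MYC targets, 2 were lower, 1 was higher in WT cells and 21 did not pass (adjusted over the list alone, 3 were lower and 1 was higher in WT cells), with camera adjusted p = 0.0012, and adjusted p = 0.22 with an estimated correlation. ODC1 (-0.65 ± 0.12) and WDR43 (-0.52 ± 0.11) were lower, and LDHA was higher (0.60 ± 0.12). Of 19 adhesion and matrix genes, 3 were lower, 1 was higher in WT cells and 15 did not pass (adjusted over the list alone, 8 were lower and 2 were higher in WT cells), with camera adjusted p = 0.014, and adjusted p = 0.32 with an estimated correlation. ITGA2 (-1.44 ± 0.13), ITGB5 (-0.90 ± 0.15) and COL12A1 (-0.77 ± 0.17) were lower and LAMA3 higher (0.89 ± 0.20). Of 18 MLL-ENL targets of leukaemia, 1 was higher in WT cells and 17 did not pass (adjusted over the list alone, 3 were higher in WT cells), with camera adjusted p = 0.016, and adjusted p = 0.31 with an estimated correlation. BCL2 was the called member (0.69 ± 0.15). Of 24 p53 targets, 1 was lower, 1 was higher in WT cells and 22 did not pass (adjusted over the list alone, 3 were lower and 1 was higher in WT cells), with camera adjusted p = 0.044, and adjusted p = 0.41 with an estimated correlation. The test pointed down; BTG2 (0.60 ± 0.12) was higher and ZMAT3 (-0.83 ± 0.17) lower. Of 23 ATF4 and unfolded protein genes, 1 was higher in WT cells and 22 did not pass (adjusted over the list alone, 5 were lower and 2 were higher in WT cells), with camera adjusted p = 0.026, and adjusted p = 0.41 with an estimated correlation. This test too pointed down, with 4 of 23 members above 0, while the called member VLDLR was higher (0.89 ± 0.16). The following were not called in fits with 1 library fewer, with signs kept: BTG2, ITGB5, COL12A1, LAMA3, ODC1, WDR43, LDHA, BCL2, ZMAT3 and VLDLR without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.29). COL12A1 was not called with library totals alone, with a CPM of at least 1 in 2 libraries, with libraries thinned to the smallest, with DESeq2 size factors or with protein-coding genes alone (adjusted p up to 0.18). LAMA3 was not called with library totals alone, with a replicate block or with libraries thinned to the smallest (adjusted p up to 0.13). WDR43 was not called with library totals alone or with a replicate block (adjusted p up to 0.075). BCL2 was not called with library totals alone, with no filter on low counts, by limma-voom, with a replicate block or with libraries thinned to the smallest (adjusted p up to 0.065). ZMAT3 was not called with library totals alone or with libraries thinned to the smallest (adjusted p up to 0.11).

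List calls of the difference rested on single libraries in places. The adhesion test was not called without WT_shXPO6 replicate 2 (camera adjusted p = 0.18). The ATF4 test ended without WT_shLUC replicate 1 or Res_shLUC replicate 2 (0.061 and 0.052), and the MLL-ENL test without WT_shLUC replicate 2, WT_shXPO6 replicate 1, Res_shLUC replicate 2 or Res_shXPO6 replicate 1 (0.071, 0.11, 0.052 and 0.081). The p53 test ended without WT_shLUC replicate 1, either WT_shXPO6 library, either Res_shLUC library or Res_shXPO6 replicate 1, at adjusted p up to 0.13. Oestrogen receptor targets were not called as a list; of 24, 4 were higher and 2 were lower (5 were higher and 3 were lower adjusted over the list alone, camera adjusted p = 0.31), and PGR (1.76 ± 0.15), CA12 (0.66 ± 0.11) and STC2 (0.64 ± 0.11) were higher while TFF1 (-1.20) was lower. Leaving out 1 library ended calls, with no change of sign: CA12 and STC2 without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.15).

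In all, the difference was positive for 339 genes and negative for 228 (edgeR QL, BH), 220 and 104 of them by more than 2-fold. Of the 339, 247 fell in RNAi-resistant cells, 143 rose in WT cells and 259 were higher in RNAi-resistant cells under shLUC. Of the 228, 139 fell in WT cells and 114 rose in RNAi-resistant cells. Counts were 1726 and 1976 without WT_shXPO6 replicate 2, and 2300 and 3855 without its replicate 1. Without WT_shLUC replicate 1 or 2 they were 131 and 48 or 129 and 49, without Res_shLUC replicate 1 or 2 127 and 44 or 142 and 49, and without Res_shXPO6 replicate 1 or 2 127 and 52 or 125 and 49. With no filter on low counts they were 527 and 560, with GC content and length offsets 610 and 874, and by the DESeq2 Wald test 447 were negative. A fit without either WT_shXPO6 library holds 1 library of that group and not the spread of its pair. The larger counts in those fits therefore do not show that the calls are stable.

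**Figure D4:**
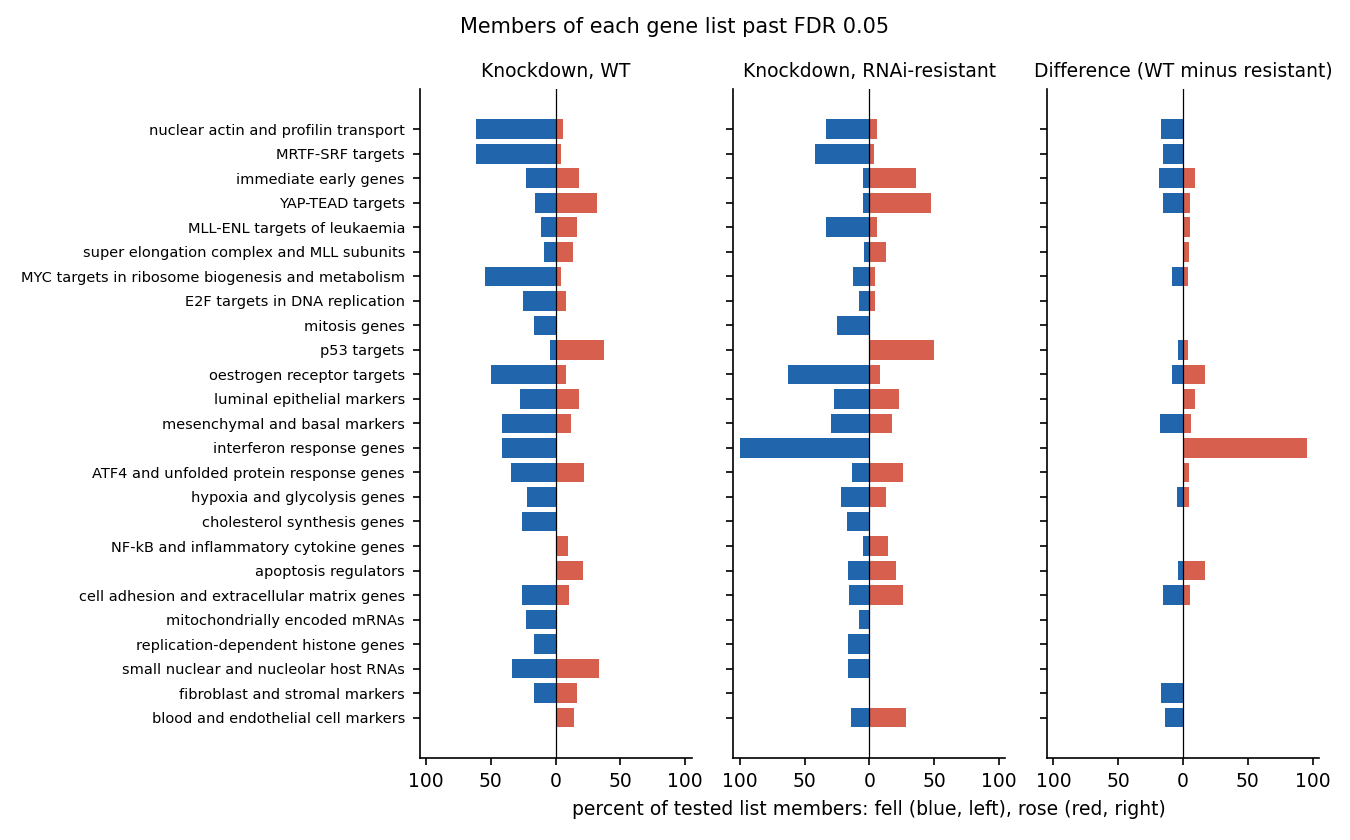
Percent of the tested members of each gene list that fell (blue, to the left) or rose (red, to the right) in the 3 comparisons, knockdown in WT cells, knockdown in RNAi-resistant cells and their difference, called by edgeR QL at a BH adjusted p under 0.05. In RNAi-resistant cells 24 of 24 interferon response genes fell, and 23 of 24 were higher in the difference.

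The direct comparison under shXPO6 sets RNAi-resistant against WT cells with the same shRNA. IFI44L was higher in RNAi-resistant cells, at 7.08 ± 0.86 against 0.408 ± 0.24 CPM (log2 fold change 4.30 ± 0.25, n = 2 per group, edgeR QL, BH adjusted p = 1.6e-05). TGM2 was 11.6-fold higher (3.54 ± 0.30, adjusted p = 9.6e-05), and SPOCK1, ARHGAP36 and MGP followed (3.34, 3.27 and 3.14). Lower were the plexin gene PLXNA4 (-3.43 ± 0.15, adjusted p = 3.9e-06), MALRD1, UNC5C, SLC27A6 and MUC1 (-3.09, -3.07, -2.86 and -2.84). PFN1 (-0.06 ± 0.26), PFN2 (0.34 ± 0.15), ACTB (0.23 ± 0.15), IPO9 (-0.16 ± 0.08) and MYC (0.06 ± 0.15) did not pass (adjusted p = 0.90, 0.13, 0.32, 0.23 and 0.81). Without WT_shXPO6 replicate 1, IFI44L stood at 3.63, TGM2 at 5.15, SPOCK1 at 3.98, ARHGAP36 at 5.87 and MGP at 4.50. In that fit PFN1 stood at 0.58, PFN2 at 0.66, ACTB at 0.52 and MYC at 0.40. Without WT_shXPO6 replicate 2, IFI44L stood at 4.89, ARHGAP36 at 2.65 and SLC27A6 at -2.06. PFN1 then stood at -0.49, PFN2 at 0.11, ACTB at -0.0014, IPO9 at -0.19 and MYC at -0.19. Either fit holds 1 WT_shXPO6 library, so p-values are not given. PFN2 was called with library totals alone and with no filter on low counts (adjusted p up to 0.040). IPO9 was called with GC content and length offsets (adjusted p = 0.018).

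Of 24 interferon response genes, 18 were higher (20 higher adjusted over the list alone), IFI27 (2.69) and BST2 (3.02) among them. Of 22 immediate early genes, 14 were higher (14 higher adjusted over the list alone); FOSL1 (2.47) and JUNB (1.09) were higher. Of 21 NF-kB genes, 12 were higher (13 higher adjusted over the list alone), including ICAM1 (2.24), TNFAIP3 (1.70) and CSF1 (1.71). Of 26 MRTF-SRF targets, 10 were higher and 2 lower (10 higher and 3 lower adjusted over the list alone); CNN2 (1.03), CCN1 (1.22) and TPM4 (0.65) were higher and TPM1 (-0.86) was lower. Of 17 mesenchymal and basal markers, 9 were higher and 1 lower (9 higher and 1 lower adjusted over the list alone); TP63 was higher (2.19) and CD44, chosen after values were seen, lower (-0.45 ± 0.10). Among cell cycle genes, of 24 mitosis genes, 17 were lower (17 lower adjusted over the list alone), of 24 E2F targets, 1 was higher and 8 lower (1 higher and 10 lower adjusted over the list alone) and of 18 replication-dependent histone genes, 13 were lower (14 lower adjusted over the list alone). AURKB (-1.05), KIF23 (-0.74), MCM4 (-0.87) and RRM2 (-0.91) were lower, and CCNE1, chosen after values were seen, was higher (1.09 ± 0.20). With library totals alone 9 mitosis genes were lower. Calls that ended, at the same sign, when 1 library was left out were CCNE1 and CD44 without either Res_shXPO6 library (adjusted p up to 0.15). CCNE1 and CD44 were not called in a fit to the comparison's own 4 libraries (adjusted p up to 0.11).

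In all, 1706 genes were higher and 1487 lower in RNAi-resistant cells under shXPO6 (edgeR QL, BH), 704 and 310 by more than 2-fold. Counts were 3115 and 3205 without WT_shXPO6 replicate 2, 4956 and 3900 without its replicate 1, and 678 and 397 or 676 and 401 without Res_shXPO6 replicate 1 or 2. Without WT_shLUC replicate 1 or 2 the counts of lower genes were 858 or 862, and without Res_shLUC replicate 1 or 2, 856 or 869. The counts of higher genes were 1160, 1167, 1087 and 1101 in these fits. In a fit to the 4 libraries of this comparison 561 were higher and 374 lower, and with GC content and length offsets 3218 were lower.

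The direct comparison under shLUC gives the baseline difference of the lines, which were made by separate infections. Interferon response genes were higher in RNAi-resistant cells. IFI44L was higher, at 177 ± 3.0 against 0.459 ± 0.045 CPM (log2 fold change 8.57 ± 0.21, n = 2 per group, edgeR QL, BH adjusted p = 3.3e-08). IFI44, MX2, UBA7 and APOL6 followed (6.89, 6.42, 5.74 and 5.59). Of 24 interferon response genes, 24 were higher (24 higher adjusted over the list alone), and so were 11 of 21 NF-kB genes (16 higher adjusted over the list alone), BCL3 (0.94) and ICAM1 (2.51) among them. ADORA1 was lower (-4.90 ± 0.20, adjusted p = 6.7e-07), with KCNJ3, SLC16A2, DRD1 and FAM178B (-3.66, -2.83, -2.81 and -2.72). Of 24 mitosis genes, 11 were lower (19 lower adjusted over the list alone); of 18 histone genes, 13 were lower (13 lower adjusted over the list alone); and of 24 E2F targets, 1 was higher and 9 lower (1 higher and 10 lower adjusted over the list alone). Of 24 MYC targets, 10 were lower (12 lower adjusted over the list alone). AURKB was lower (-0.83 ± 0.14) and CCNE1, chosen after values were seen, higher (0.64 ± 0.19). With library totals alone 5 mitosis genes and 6 MYC targets were lower. CCNE1 was not called with libraries thinned to the smallest (adjusted p = 0.072).

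Among the fixed genes, IPO9 was lower in RNAi-resistant cells under shLUC (-0.31 ± 0.08, adjusted p = 0.028 by edgeR QL and BH). PFN1 (-0.65 ± 0.26), PFN2 (0.07 ± 0.14), ACTB (-0.31 ± 0.15) and MYC (-0.09 ± 0.15) did not pass (adjusted p = 0.11, 0.78, 0.18 and 0.74). No longer called with 1 library left out, at the same sign, were IPO9 and CCNE1 without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.31) and AURKB without Res_shLUC replicate 2 (adjusted p = 0.061). PFN1 (-0.65) and ACTB (-0.31) were called without either WT_shXPO6 library (adjusted p up to 9.5e-10). IPO9 was not called with library totals alone (adjusted p = 0.11). PFN1 and ACTB were called in a fit to the comparison's own 4 libraries, with no filter on low counts and with GC content and length offsets (adjusted p up to 0.014). In all, 1737 genes were higher and 1704 lower, 868 and 238 by more than 2-fold. With library totals alone these were 1946 and 1040, or 65.2% higher against 50.5%. Of the 3441 genes, 1659 differed in the same direction under shXPO6 and 67 in the opposite one. Counts were 3811 and 4166 without WT_shXPO6 replicate 2, 3791 and 4171 without its replicate 1, 703 and 501 or 695 and 519 without WT_shLUC replicate 1 or 2, and 715 and 461 or 743 and 435 without Res_shLUC replicate 1 or 2. Without Res_shXPO6 replicate 1 or 2 the counts of lower genes were 1095 or 1098, against 1188 or 1183 higher. In a fit to the 4 libraries of this comparison 4096 were higher and 4232 lower, and with GC content and length offsets 3812 were lower.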

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

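The tests of immune cell markers, of effects proportional to the fall of XPO6 and of an shRNA effect that the transgene does not prevent were chosen after their results were seen. The knockdown effect differed between WT and RNAi-resistant cells by edgeR's test of the difference for 567 genes, higher in WT cells for 339 and lower for 228.

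Most genes moved the same way in both lines although the transgene escapes the shRNA. Of the genes called in WT cells, 88.15% had the same sign in RNAi-resistant cells, a share that cannot tell an effect of the shRNA that the transgene does not prevent from a response to the remaining fall of XPO6. After a trend on GC content and length was taken from both effects the share was 85.38%, which argues against that bias as the source. XPO6 itself changed 0.347 times as much on the log2 scale in RNAi-resistant as in WT cells (upper 95% bound 0.484). The median ratio of effects was 0.596 over the genes called in WT cells (0.573 to 0.613 by resampling genes), above that bound. The genes share the same 8 libraries, so this interval leaves out the spread between libraries. Within that limit the ratio argues against effects proportional to the fall of XPO6 mRNA, for those genes only. It ran from 0.557 to 0.619 over the settings. Over the 2943 genes called in RNAi-resistant cells it was 1.17, so it depends on which line chose the genes. Over all tested genes, most of them not called, it was 0.440 and ran from 0.203 to 0.511. The test therefore says nothing of genes that were not called. A response to the remaining fall of XPO6 that is not proportional, an off-target effect of the shRNA, and differences of transgene expression between cells stay open, since protein was not measured and 1 shRNA was used.

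Interferon response genes fell in RNAi-resistant cells and much less in WT cells, with a median difference of 2.04 over the list. The members that were at 5 CPM or more in WT_shLUC showed a median of 16.63% of the RNAi-resistant fall in WT cells (quartiles 2.19% and 28.3%, 21 members), which argues against a count floor in WT cells as the source of the gap. Markers of blood and endothelial cells summed to 0.9205 times the WT_shLUC level in Res_shLUC (14.8 and 15.5 against 16.8 and 16.1 CPM). Of the 13 markers 7 were tested, and they moved both ways: CD68 (4.99 against 7.99 CPM) and CDH5 (0.888 against 4.10 CPM) were lower and HLA-DRA, which interferon also induces, was higher (6.92 against 1.27 CPM). The sum therefore excludes nothing, and immune cells mixed into that group stay open. Under shXPO6, without Res_shLUC samples, the list was higher in RNAi-resistant cells by a median of 0.9602 (log2), against 3.09 under shLUC. With 23 of 24 members above 0 and 18 called, this argues against a state of those samples alone. A lasting state of the line stays open, as the value lies between the bounds set and the labels name 1 line of each kind. So does a knockdown effect on an active interferon program.

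WT_shXPO6 replicate 2 stood apart from its partner. With all libraries thinned to its depth, the median absolute log2 difference of the pair was still 2.759 times that of the widest other pair, which argues against lower depth. GC content and length explained 20.5% of the variance of the log2 difference, and the median left after the trend was 0.217, against raw values of 0.08 to 0.11 in the other groups, so that trend is not the whole cause. The slope of replicate 2 minus replicate 1 on the RNAi-resistant effect was -0.03875 (-0.0591 to -0.0173, resampling 2761 genes). The lines' effects differ, so further progress in WT cells stays open. So does a difference of culture or library preparation, not tested as no labels give batches.

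The log2 difference of the effects, WT minus RNAi-resistant, was positive for CD74 (4.29), APOL1 (4.15), RSAD2 (4.09) and MX2 (3.72), and for IFI44 (4.38), IFIT3 (4.37), IFI44L (4.27), SECTM1 (4.01), UBA7 (3.97), CCL5 (3.82), HERC5 (3.82), TNFSF10 (3.59), IFIT2 (3.50), TRANK1 (3.35), NLRC5 (3.21), OAS2 (2.95), CMPK2 (2.93) and ARHGAP24 (2.23). Further positive values were those of IFIT1 (2.16), PCDH19 (1.82), PGR (1.76), PLXNA4 (1.70), KRT17 (1.62), CYP1A1 (1.51), STAT1 (1.28), MX1 (1.01), BMF (0.91), VLDLR (0.89), LAMA3 (0.89), MLLT3 (0.83), KLF4 (0.78), BCL2 (0.69), SPDEF (0.68), ESR1 (0.68), CA12 (0.66), STC2 (0.64), BTG2 (0.60), LDHA (0.60) and CRIM1 (0.57). It was negative for ADORA1 (-3.67), KRT81 (-3.15), TFF1 (-1.20) and XPO6 (-0.88) and for SPOCK1 (-2.55), PADI3 (-2.27), GABBR2 (-2.24), LOXL2 (-2.23), MMD (-2.23), S100A16 (-2.14), NAV2 (-2.12), TNIK (-2.10), FOXI1 (-1.71), CEACAM5 (-1.50), ITGA2 (-1.44), FHL2 (-1.37), FOSL1 (-1.21), EGR3 (-1.14), IER3 (-1.11), CFL2 (-1.11), CCN2 (-0.998) and TPM4 (-0.91). Smaller negative values were those of LAMC2 (-0.91), ITGB5 (-0.90), CCN1 (-0.89), AREG (-0.83), ZMAT3 (-0.83), KLF6 (-0.78), COL12A1 (-0.77), TMSB4X (-0.73), LAMB3 (-0.68), ODC1 (-0.65), AMOTL1 (-0.63), BCL2L11 (-0.61) and WDR43 (-0.52). Without 1 library, 39 of these 74 calls ended at the same sign: MX1, BMF, VLDLR, LAMA3, MLLT3, KLF4, BCL2, SPDEF, ESR1, CA12, STC2, BTG2, LDHA, CRIM1, WDR43, BCL2L11, AMOTL1, ODC1, LAMB3, TMSB4X, COL12A1, KLF6, ZMAT3, AREG, XPO6, CCN1, ITGB5, LAMC2, CCN2, CFL2, FHL2 and TNIK without each of the 6 libraries outside WT_shXPO6 (adjusted p up to 0.32), ARHGAP24 without either WT_shLUC library, either Res_shXPO6 library or Res_shLUC replicate 1 (adjusted p up to 0.093), CYP1A1 without Res_shXPO6 replicate 1 (adjusted p = 0.058), CEACAM5 without either WT_shLUC library, either Res_shLUC library or Res_shXPO6 replicate 1 (adjusted p up to 0.10), FOXI1 without Res_shLUC replicate 2 (adjusted p = 0.052), MMD without Res_shLUC replicate 1 (adjusted p = 0.0502), PADI3 without Res_shLUC replicate 1, Res_shXPO6 replicate 1 or WT_shLUC replicate 1 (adjusted p up to 0.065) and SPOCK1 without Res_shLUC replicate 1, Res_shXPO6 replicate 1 or WT_shLUC replicate 2 (adjusted p up to 0.062). Of these, 19 also ended under another setting (adjusted p up to 0.18), and the other 35 held in every setting.

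Over the lists called in the difference, the median log2 difference was -0.44 for nuclear actin and profilin transport, -0.48 for MRTF-SRF targets, -0.50 for immediate early genes, 0.36 for MLL-ENL targets, -0.28 for MYC targets, -0.15 for p53 targets, -0.27 for ATF4 and unfolded protein genes and -0.36 for adhesion and matrix genes. The tests of the last 3, of the immediate early genes and of the MLL-ENL list changed with single libraries or with the test, as the comparison gives. With 1 library left out the medians moved too: without WT_shXPO6 replicate 1 to -0.75 for MRTF-SRF, -0.31 for p53 and -0.41 for ATF4 targets, without its replicate 2 to -0.24 for the actin list and 0.23 for MLL-ENL targets, and without WT_shLUC replicate 2 to -0.24 for adhesion genes. Without XPO6, the actin median was -0.42. With an estimated correlation, of the lists called in the difference the interferon list alone was called.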

How the results depend on the processing

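The offsets for GC content and length and the actin list without XPO6 were chosen after the data were seen; all other alternatives were planned. A fit to 4 libraries cannot give the difference. Named genes that were called in a comparison kept their direction there in every setting, and among those not called PFN1 and MYC under shXPO6 reversed past the threshold; gene results changed a call in 299 cases to a lost call and 41 to a gained one, with 4864 unchanged.

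With the fits to 4 libraries, WT counts were 344 risen and 352 fallen, RNAi-resistant 3744 and 3650, under shXPO6 561 and 374, under shLUC 4096 and 4232, and 608 genes were called in both knockdowns in the same direction. Each such fit takes its spread from 2 groups, and those with WT_shXPO6 held its wide pair. With library totals alone 1113 genes fell in WT cells and 1040 were lower under shLUC, as no scaling for RNA composition was made. With no filter on low counts the difference had 527 higher and 560 lower genes, and 659 genes were called in WT cells and in the difference; with the DESeq2 Wald test these were 447 lower and 554. With GC content and length offsets 2355 genes rose in RNAi-resistant cells, the difference had 610 higher and 874 lower, 3218 were lower under shXPO6, 3812 lower under shLUC, 2418 were called in both knockdowns and 988 in WT cells and in the difference. For the values with no filter, with DESeq2 and with the offsets the cause was not tested.

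Leaving out 1 library gave 436 to 3752 risen and 592 to 4789 fallen genes in WT cells, 453 to 3712 and 557 to 3697 in RNAi-resistant cells, 125 to 2300 and 44 to 3855 in the difference, 676 to 4956 and 397 to 3900 under shXPO6, and 695 to 3811 and 435 to 4171 under shLUC. Genes called in both knockdowns ranged from 588 to 3948, and in WT cells and the difference from 69 to 4687. A lone sample was assumed to vary like the others, and the extremes follow WT_shXPO6: without either of its libraries, the fit holds no wide pair, and without another library that pair weighs more on 3 residual degrees of freedom. XPO6 ranged from -1.48 to -1.25 in WT cells, -0.48 to -0.45 in RNAi-resistant cells, -1.01 to -0.79 in the difference, 1.48 to 1.70 under shXPO6 and 0.66 to 0.73 under shLUC; its call ended in RNAi-resistant cells without 4 libraries and in the difference without 6. PFN1 under shXPO6 ranged from -0.49 (without WT_shXPO6 replicate 2) to 0.58 (without replicate 1), and MYC from -0.19 (without WT_shXPO6 replicate 2) to 0.40 (without replicate 1), so both reversed. The number of called lists was 10 to 14 in WT cells, 8 to 9 in RNAi-resistant cells and 6 to 9 in the difference.

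With an estimated correlation the lists called in WT cells were 0, 1 in RNAi-resistant cells and 1 in the difference (13, 8 and 9 with the preset correlation; fry called 16, 17 and 10); this estimate rests on 4 residual degrees of freedom. Of the list results, 51 lost a call, 22 gained one and 830 kept their side. A replicate block gave 1570 risen and 1868 fallen in WT cells, 1469 and 1458 in RNAi-resistant cells and 323 and 237 in the difference. Simulated 1.5-fold changes were recovered in 31.3% of genes in WT cells, with the same spread in every group, which the data did not have.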

Other observations

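None of the tests in this part was chosen after its result was seen. Genes of adhesion moved in both directions. Of 19 adhesion and matrix genes, 2 rose and 5 fell (6 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.48) in WT cells, and 5 rose and 3 fell (5 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.093) in RNAi-resistant cells. LAMB1 stood at 1.95 ± 0.13 in WT and 2.45 ± 0.13 in RNAi-resistant cells, and COL12A1 at 1.24 ± 0.12 and 2.01 ± 0.12 (edgeR QL, BH adjusted p = 3.3e-05, 6.1e-06, 0.00026 and 1.2e-05). Of 24 apoptosis regulators, 5 rose (5 rose adjusted over the list alone, camera adjusted p = 0.067) in WT cells, BMF among them (1.69 ± 0.12), and 5 rose and 4 fell (5 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.28) in RNAi-resistant cells, where BCL2L11 rose (0.58 ± 0.08). Of 23 ATF4 and unfolded protein response genes, 6 rose and 3 fell (6 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.29) in RNAi-resistant cells; PHGDH stood at 0.73 ± 0.08 and DDIT3 at 1.04 ± 0.18. Some calls ended at an unchanged sign with 1 library fewer: DDIT3 without either Res_shLUC library (adjusted p up to 0.057). The nuclear RNAs MALAT1 (0.97 ± 0.15) and NEAT1 (0.77 ± 0.12) rose in WT cells; of 6 small nuclear and nucleolar host RNAs, 2 rose and 2 fell (3 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.87). The following were not called in fits with 1 library fewer, with signs kept: NEAT1 without WT_shLUC replicate 1 (adjusted p = 0.054). MALAT1 and NEAT1 were not called in a fit to the comparison's own 4 libraries (adjusted p up to 0.062). By fry the apoptosis list was called in WT cells (adjusted p = 0.0045) and the adhesion list in RNAi-resistant cells (0.0053).

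In WT cells, of 23 super elongation complex and MLL subunits, 3 rose and 2 fell (3 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.70); of 18 replication-dependent histone genes, 3 fell (3 fell adjusted over the list alone, camera adjusted p = 0.083); of 6 fibroblast and stromal markers, 1 rose and 1 fell (1 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.98); and of 7 blood and endothelial cell markers, 1 rose (1 rose adjusted over the list alone, camera adjusted p = 0.98). The histone list was called without WT_shLUC replicate 2 (adjusted p = 0.034) or WT_shXPO6 replicate 1 (0.046), and by fry (0.024). With library totals alone, the medians of the mitosis, histone, blood, MLL-ENL and super elongation lists had the opposite sign in WT cells. In RNAi-resistant cells, of 18 MLL-ENL targets of leukaemia, 1 rose and 6 fell (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.093); of 23 super elongation complex and MLL subunits, 3 rose and 1 fell (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.41); of 24 MYC targets, 1 rose and 3 fell (3 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.23); of 24 E2F targets in DNA replication, 1 rose and 2 fell (2 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.22); of 22 luminal epithelial markers, 5 rose and 6 fell (6 fell and 6 rose adjusted over the list alone, camera adjusted p = 0.29); of 17 mesenchymal and basal markers, 3 rose and 5 fell (5 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.15); of 23 hypoxia and glycolysis genes, 3 rose and 5 fell (8 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.14); of 21 NF-kB and inflammatory cytokine genes, 3 rose and 1 fell (4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.26); of 18 replication-dependent histone genes, 3 fell (4 fell adjusted over the list alone, camera adjusted p = 0.14); and of 7 blood and endothelial cell markers, 2 rose and 1 fell (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.26). Of these, the lists of MLL-ENL targets, super elongation subunits, luminal, basal, hypoxia, histone and blood genes were called by fry (adjusted p up to 0.044). Among lists whose test, median and mean differed in sign in WT cells, fibroblast markers had a median of 0.03, a mean of 0.39 and a test pointing down, and blood markers had -0.12, -0.16 and a test pointing up. For small nuclear RNAs the median was -0.16, the mean -0.01 and the test pointed up. With 1 library left out these medians ran from -0.51 to 0.27, from -0.21 to -0.01 and from -0.17 to -0.05. Of 10 HEK293 packaging line markers 3 were tested, and their summed level was 4.81 to 14.4 CPM over the 8 libraries.

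Differences between the lines that run along a chromosome were tested as a sign of copy number. Windows of 10 Mb with at least 10 genes (286 windows, 12366 genes) were compared between RNAi-resistant and WT cells, and 5 windows passed every bound set: a median log2 difference beyond 0.4 in the same direction under shLUC and under shXPO6, and knockdown medians within 0.2. The largest joint value in 100 random orders of the genes was 0.36. On chromosome 1, the windows at 90 to 100, 100 to 110 and 110 to 120 Mb had medians of 0.55, 0.76 and 0.58 under shLUC, and 0.60, 0.78 and 0.55 under shXPO6. Windows at 110 to 120 Mb of chromosome 8 (-0.52 and -0.53) and 50 to 60 Mb of chromosome 6 (-0.40 and -0.53) were lower. Across windows the Pearson correlation of both comparisons was 0.755, against 0.545 for the knockdown effects. The lines may therefore differ in copy number of these segments; gene expression alone cannot show this.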
